A study of Homo sapiens with 6 samples.

How the data were processed

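RNA-seq was performed on MCF-7 cells, an oestrogen receptor-positive human breast cancer line, in 2 groups of 3 libraries: control cells and cells exposed to Lycium barbarum polysaccharides (LBP, from the goji berry) at 8 mg/mL for 48 h, per the labels. Total RNA was extracted with TRIzol and libraries were built with an Illumina-compatible New England Biolabs kit, per the labels' protocols. The treated libraries carry a title abbreviation that differs from LBP in its first letter and were taken as the LBP group, since the labels name no other treatment. The labels do not say whether the replicates of a group were separate cultures, or whether control cells received a vehicle, so p-values measure the spread between these libraries, which may be technical.

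The authors deposited a single table of 58735 genes. Its raw counts per gene and library were deposited without normalization, per the file headers, and were whole numbers with a different total in each library. The reads were placed on GRCh38, per the submitters' processing notes. The aligner, the counting tool and the use of strand were not given in the sources used here. All 58735 gene identifiers, with their start and end positions, were found in GENCODE release 29, and coordinates are given as in the deposited table. The authors also deposited FPKM values, which equal the count divided by gene length and by a library size proportional to the median-of-ratios size factor of the library. They deposited group means as normalized signal (counts divided by the same size factors), a log2 fold change of LBP against control, and a p-value with its adjusted p-value. The tool behind the authors' comparison was not given in the sources used here. The authors' deposited table lists an adjusted p-value of 1 for 14309 of 29519 genes, and 1318 genes below 0.05. FPKM and the authors' group means were used to check how the table was made and entered no test.

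The deposited counts were tested with the quasi-likelihood test of edgeR 4.0.16 (robust estimation) in R 4.3.3, with TMM scaling, the filterByExpr filter on low counts and Benjamini-Hochberg adjustment (FDR). A gene was called changed at an FDR below 0.05. Counts of list members that rose or fell, or were higher or lower, are counts of calls. Members outside these counts may still have changed. Standard errors of log2 fold changes were taken from the fold change and the F statistic. Levels are CPM, counts relative to the TMM-scaled library total, as mean ± SD over the 3 libraries of a group. The filter left 16011 genes, and 26463 genes had no count in any library. Total counts ran between 15301354 and 16680454 per library, at which 3 counts, taken as the floor of detection in a single library, equal 0.180 to 0.196 CPM. A fold change against a group without counts is given as a bound against 3 counts over the 3 libraries of that group. The floor covers counting error only, since the reads carried no molecular identifiers that the table shows. On simulated counts for 15659 genes drawn from these libraries, with 200 genes changed, the test recovered 70% of genes changed 2-fold and 94% of those changed 4-fold, and 7.87% of its calls were unchanged genes. Without control replicate 1, and with dispersions estimated without it, the figures over 15797 genes were 84%, 98% and 8.54%. The changed genes were drawn from those with a mean CPM of at least 1. Counts were drawn independently for each gene, so no simulated library stood apart as control replicate 1 did. The figures therefore do not show how many calls in the real libraries are false, with or without control replicate 1.

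The 35 gene lists were fixed before the data were examined, as were the design, the alternatives and the rule for naming genes. Lists with at least 5 measured members (32 of 35) were tested 2-sided with camera of limma 3.58.1, with a preset correlation of 0.01, on log2 CPM with a prior count of 2. Camera with an estimated correlation per list and fry were run beside it. Fry asks whether the members of a list move, on balance, one way, and does not compare the list with other genes. For each list, calls are also given with the FDR adjusted over the list alone. The genes named are the 8 largest rises and the 8 largest falls among called genes with a symbol, a mean CPM of at least 5 and every LBP library on one side of every control library, then 13 genes chosen for the cell line and treatment, then up to 4 members with the smallest FDR from each called list and up to 2 from each other list.

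The alternatives were edgeR with the size factors of DESeq2, with upper-quartile scaling and with total counts only; no filter and a stricter filter on low counts (a CPM of at least 1 in 3 libraries); DESeq2 1.42.0; limma-voom; the replicate number as a block; a test against a 1.5-fold change; an FDR below 0.01; and leaving out each library in turn. Shares of counts were compared with exact 2-sided permutation tests, which cannot give a p below 0.1 with 3 libraries against 3. Pairs of libraries within a group differed by more than sampling noise, with chi-square per degree of freedom between 4.9 and 58.2 over genes with at least 20 counts, so each library was counted once. Genes that share sequence with near-identical copies were treated as uncertain: the FTH1 pseudogenes, AKR1C1 with AKR1C2, the UGT1A genes, whose transcripts share exons, and the histone genes. Since the use of strand was not given, a named gene was also treated as uncertain where its span overlaps another gene with at least 10% of its counts. Among the called genes named here, these are ACSS2, AHRR, ALDOA, ALDOC, CBR3, ETV4, FTH1P23, LDLR, MAP1LC3B, NPC1, SPRY4, SQSTM1, TXNRD1 and UGT1A6, and among those not called CD19, DDIT3, DHFR, DNAJB1, ESAM, FTH1P3, GNL3, LOX, MT-ATP8, POLA1, SGK3, TP53 and TYMS. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.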

Results

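The transcriptome of MCF-7 cells was compared between 3 control libraries and 3 libraries from cells treated with LBP at 8 mg/mL for 48 h. The title of the study places the comparison in the question of how LBP slows the growth of these cells. Control replicates 1, 2 and 3 held 16680454, 15868377 and 15301354 counts, and LBP replicates 1, 2 and 3 held 15526207, 15718222 and 15887204. Control replicate 1 stood apart from the other 2 controls. The root mean square log2 difference was 0.70 and 0.73 between it and control replicates 2 and 3, against 0.38 between the latter, and 0.41 to 0.44 among the LBP libraries. Of 48 named genes that were not called, 35 were called without control replicate 1, and values without it are given beside many of the genes and lists below. Those values rest on 2 controls, which were the closest pair among all libraries. Leaving out the library that stood apart narrows the spread between controls, so calls made without it may be too many. Such calls do not show that control replicate 1 had hidden a change.

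**Figure D1:**
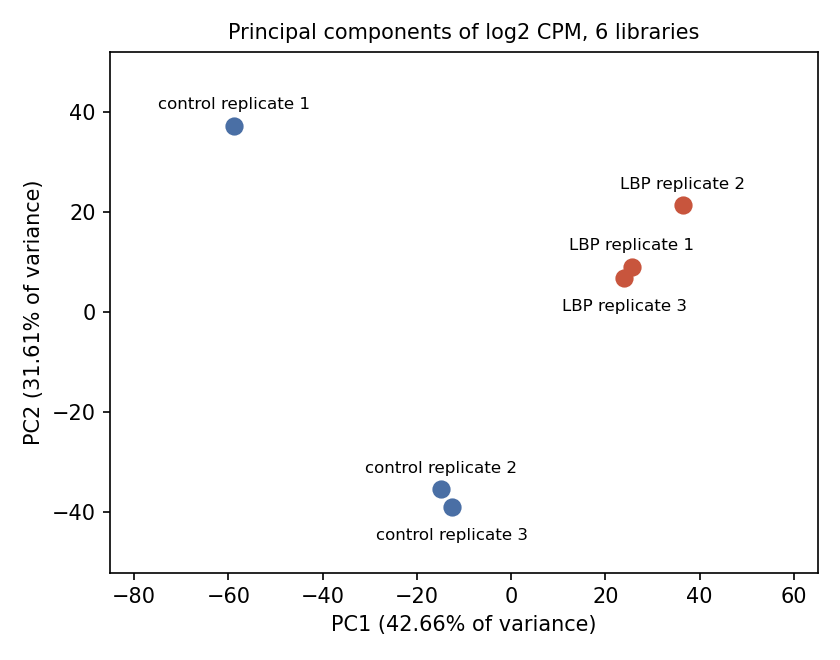
Principal components of log2 CPM over the 16011 tested genes, with 42.7% of the variance on the horizontal and 31.6% on the vertical axis; each point is 1 library. The 3 LBP libraries lie at 24.0 to 36.4 on the horizontal axis and all controls below 0, with control replicate 1 at −58.7 and away from control replicates 2 and 3 on both axes.

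Among the genes that changed most between LBP-treated and control cells, genes of the oxidative stress and xenobiotic responses were higher and an imprinted RNA and an interferon-induced gene were lower. HMOX1, which encodes the haem-degrading enzyme haem oxygenase-1 (GRCh38 chromosome 22, 35380361 to 35394214), rose 15.8-fold, between 20.8 ± 6.38 CPM in control and 328 ± 69.9 CPM in LBP (SD, n = 3). CYP1A1, a xenobiotic-metabolising cytochrome P450 (chromosome 15, 74719542 to 74725610), rose 14.3-fold, from 61.7 ± 27.1 to 882 ± 134 CPM. The imprinted non-coding RNA MEG3 (chromosome 14, 100779410 to 100861031) fell 8.97-fold, from 42.9 ± 12.7 to 4.77 ± 2.02 CPM, and the interferon-induced gene IFI6 fell 7.34-fold, from 91.6 ± 43.7 to 12.5 ± 2.43 CPM. In all, 755 of 16011 genes were called changed by the quasi-likelihood test of edgeR at an FDR below 0.05, 375 higher and 380 lower in LBP. At least 2-fold changes were called for 304 genes, 134 higher and 170 lower. With total counts as the only scaling, 278 genes were higher and 590 lower, and the median log2 fold change of all genes was −0.11 against −0.03 with TMM. The size of the set depended on single libraries. The count was 4118 without control replicate 1, of which 740 were among the 755, all in the same direction, and it was 323 without control replicate 2, 365 without control replicate 3, and 149, 104 and 256 without LBP replicates 1, 2 and 3. At least 2-fold changes numbered 804 without control replicate 1, 210 higher and 594 lower, and 120, 84 and 190 without LBP replicates 1, 2 and 3.

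**Figure D2:**
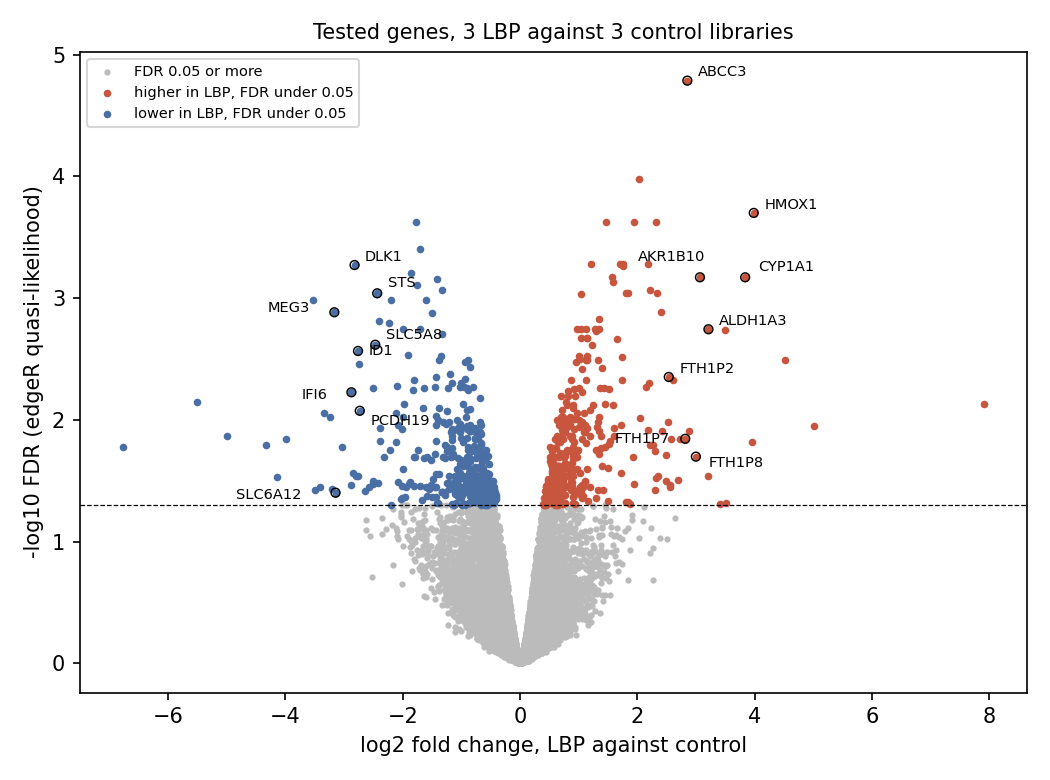
Log2 fold change of LBP against control (horizontal) and −log10 of the edgeR FDR (vertical) of the 16011 tested genes, 1 point per gene; the dashed line is an FDR of 0.05, with 375 genes above it on the right and 380 on the left. Circles mark the 8 largest rises and 8 largest falls among genes with a mean CPM of at least 5; the farthest points include genes with no count in 1 group, whose fitted change is not a bound.

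Among the 8 largest rises, HMOX1 (log2 fold change 3.98 ± 0.25, SE, FDR 0.0002) and CYP1A1 (3.84 ± 0.32, FDR 0.000674) were followed by ALDH1A3, a retinoic acid-producing aldehyde dehydrogenase (3.21 ± 0.35, FDR 0.0018), the aldo-keto reductase AKR1B10 (3.07 ± 0.27, FDR 0.000674) and the efflux transporter ABCC3 (2.85 ± 0.12, FDR 1.64e-05), all by edgeR. The other 3 were FTH1P8, FTH1P7 and FTH1P2, processed pseudogenes of the ferritin heavy chain gene FTH1, with log2 fold changes of 3.00, 2.82 and 2.54. Reads of FTH1 can be counted on such copies, so these values are uncertain. Besides MEG3 (−3.17 ± 0.32, FDR 0.00131), the largest falls were in the betaine and GABA transporter SLC6A12 (−3.15 ± 0.69, FDR 0.0396), IFI6 (−2.88 ± 0.38, FDR 0.00593), the imprinted gene DLK1 (−2.82 ± 0.23, FDR 0.000535), ID1, an inhibitor of basic helix-loop-helix transcription factors (−2.76 ± 0.32, FDR 0.00272), the protocadherin PCDH19 (−2.73 ± 0.39, FDR 0.00842), the monocarboxylate transporter SLC5A8 (−2.47 ± 0.29, FDR 0.00242) and steroid sulfatase, STS (−2.44 ± 0.23, FDR 0.000913). Of these 16 genes, 5 lost their call when 1 library was left out. FTH1P8 had an FDR of 0.133, FTH1P7 of 0.0975 and PCDH19 of 0.0525 without control replicate 1, and both pseudogenes also lost the call without control replicate 2 (0.0791 and 0.0518) and LBP replicate 2 (0.117 and 0.0743), FTH1P8 also without LBP replicate 3 (0.0663). IFI6 lost it without LBP replicate 2 (0.0505), and SLC6A12 kept it only without control replicate 1 (FDR 0.0655 to 0.199 without each other library). The log2 fold change of SLC6A12 was −2.25 without control replicate 2, and that of FTH1P8 was 3.81 without control replicate 3.

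**Figure D3:**
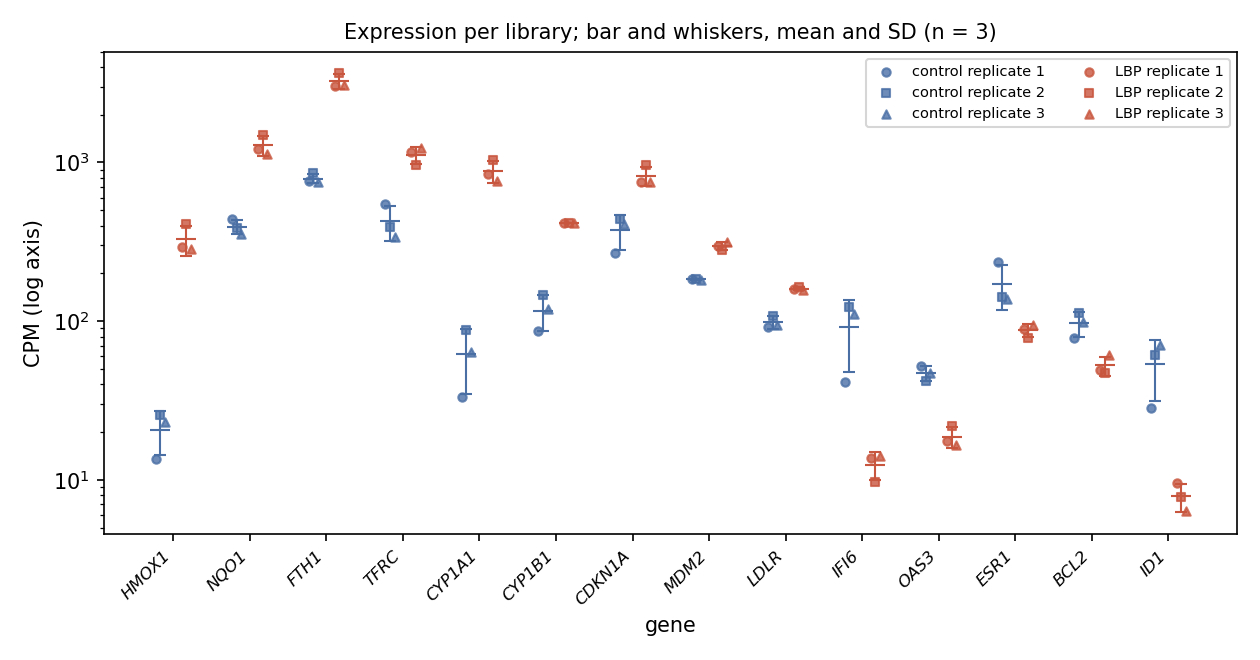
CPM of 14 named genes on a log axis, 1 point per library, with the mean (bar) and SD (whiskers, n = 3) of control and LBP. The 3 LBP libraries lie above the 3 controls for HMOX1 to LDLR and below them for IFI6 to ID1.

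Targets of NRF2, the transcription factor of the oxidative stress response, formed the list with the smallest camera FDR (2.53e-20, adjusted p = 0.195 with an estimated correlation). Of 22 measured members 16 rose and none fell, 20 rose with the FDR adjusted over the list alone, and the median log2 fold change was 1.22. Besides HMOX1, FTH1 rose 4.10-fold, from 792 ± 54.3 to 3249 ± 342 CPM (SD, n = 3; edgeR FDR 0.000104), the pentose phosphate pathway enzyme TKT rose 2.77-fold (FDR 0.000236) and the quinone reductase NQO1 rose 3.25-fold (FDR 0.000524). The cystine transporter gene SLC7A11 was at 97.2 ± 69.6 CPM in control and 228 ± 33.3 CPM in LBP and was not called (log2 fold change 1.23 ± 0.63, FDR 0.3), but it was called without control replicate 1, at a smaller log2 fold change of 0.74 (FDR 0.00072). Fry gave the list an adjusted p of 0.00194. All 22 members rose without control replicate 1, and 10 without LBP replicate 2.

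The aryl hydrocarbon receptor list, which holds the dioxin-inducible genes, was higher as well (camera FDR 2.51e-10, adjusted p = 0.134 with an estimated correlation, median log2 fold change 1.83). Of 7 measured members 6 rose, and all 7 rose with the FDR adjusted over the list alone or without control replicate 1. NQO1 is shared with the NRF2 list. The cytochrome P450 gene CYP1B1 rose 3.56-fold, from 117 ± 29.6 to 415 ± 0.923 CPM (FDR 0.000911), and AHRR, the repressor of the receptor, rose 1.97-fold (FDR 0.0018). By fry the adjusted p was 0.000958. In control replicate 1 the median of the list lay 0.60 (log2) below the mean of control replicates 2 and 3, and in the LBP libraries 1.66 to 2.01 above it.

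Genes of ferroptosis regulation and iron handling overlapped with the NRF2 list in FTH1, HMOX1, FTL and SLC7A11. Of 20 measured members 5 rose and none fell (7 with the FDR adjusted over the list alone, camera FDR 0.001, adjusted p = 0.195 with an estimated correlation, median 0.28). Ferritin light chain, FTL, rose 2.33-fold (FDR 0.00241) and the transferrin receptor TFRC rose 2.63-fold, from 425 ± 106 to 1119 ± 135 CPM (FDR 0.00378). GPX4, the lipid peroxide-reducing enzyme, was at 252 ± 26.1 and 284 ± 11 CPM and was not called (FDR 0.397), though without control replicate 1 its FDR was 0.0183 and its log2 fold change 0.26, against 0.17. The adjusted p of the list was 0.00388 by fry, and 9 members rose and 1 fell without control replicate 1. FTH1, HMOX1, TKT, NQO1, CYP1A1, CYP1B1, AHRR, FTL and TFRC kept their calls with each of the 6 libraries left out.

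Targets of p53 were higher in LBP, with 10 of 23 measured members rising and none falling (16 higher and 1 lower with the FDR adjusted over the list alone, camera FDR 2.51e-10, adjusted p = 0.262 with an estimated correlation, median 0.71). PHLDA3 rose 2.17-fold (FDR 0.00324), the antiproliferative gene BTG2 2.56-fold (FDR 0.00545), the exonuclease gene AEN 1.88-fold (FDR 0.00559) and MDM2, which encodes the ubiquitin ligase of p53, 1.63-fold (FDR 0.00634). CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, rose 2.20-fold, from 375 ± 91.7 to 823 ± 116 CPM (FDR 0.0116), and lost the call without LBP replicate 2 (FDR 0.0856). TP53 itself was at 113 ± 6.24 and 103 ± 1.26 CPM and was not called (FDR 0.456). The adjusted p of the list was 0.0246 by fry, and 15 members rose without control replicate 1 and 4 without LBP replicate 2.

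Among 29 apoptosis regulators, BAX, which promotes cell death, rose 1.63-fold (FDR 0.0102), the anti-apoptotic BCL2 fell 1.84-fold, from 96.9 ± 17.2 to 52.6 ± 7.26 CPM (FDR 0.0167), and the pro-apoptotic BMF fell 1.73-fold (FDR 0.0359). BBC3, another pro-apoptotic gene, had a log2 fold change of 1.25 ± 0.30 (FDR 0.0512; 0.0148 without control replicate 1), and CASP3, the executioner caspase gene, of 0.09 ± 0.18 (FDR 0.814). BAX, BBC3, FAS and TNFRSF10B also belong to the p53 list, and BAX was the only member of the apoptosis list called higher. The apoptosis list was called higher (camera FDR 0.0284, median 0.10), with members moving both ways. With the FDR adjusted over the list alone, 7 of its members were higher and 2 lower. Its adjusted p was 0.262 with an estimated correlation, and 0.0346 by fry. The camera call was lost without control replicate 3 (0.0929) and LBP replicate 2 (0.0572). BAX lost its call without LBP replicate 2 (FDR 0.0788), BCL2 without control replicate 2 (0.0514) and LBP replicates 1 and 2 (0.108 and 0.128), and BMF kept it only without control replicate 1 (0.107 to 0.176 otherwise). With control replicate 1 left out, 10 members rose and 2 fell.

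The proliferation lists did not give a stable direction. Of 27 DNA replication and G1/S genes only POLE2, a subunit of DNA polymerase epsilon, was called (1.68-fold lower, FDR 0.0205). The log2 fold change was negative for 26 members and positive for 1. POLE2 kept its call only without control replicates 1 and 3 (FDR 0.068 to 0.117 without each other library). POLA1, DHFR and CDC45 had log2 fold changes of −0.59, −0.81 and −0.77 and were not called (FDR 0.059, 0.119 and 0.121), but were called lower without control replicate 1 (0.00637, 0.0182 and 0.0493), where their log2 fold changes were smaller, at −0.42, −0.35 and −0.41. The list was called lower (camera FDR 0.0116, median −0.45; 2 lower with the FDR adjusted over the list alone), with an adjusted p of 0.854 with an estimated correlation and 0.536 by fry. Without control replicate 1, its median was −0.01 and its camera FDR 0.813, with 5 members higher and 4 lower. The call was also lost without LBP replicate 3 (0.075). In control replicate 1 the median of the list lay 1.03 (log2) above the mean of control replicates 2 and 3, while the LBP libraries lay between −0.11 and 0.07. None of 27 G2/M and mitosis genes was called, over all genes or over the list alone (camera FDR 0.352, adjusted p = 0.854 with an estimated correlation, median −0.15). The list was called lower without control replicate 3 (camera FDR 0.044). Without control replicate 1 its median was 0.07 and it was not called (camera FDR 0.285). ASPM and CENPE had log2 fold changes of −0.51 and −0.39 (FDR 0.0933 and 0.123) and were called lower without control replicate 1 (0.0177 and 0.0424), where 3 members of their list were higher and 2 lower. MKI67, the gene of the Ki-67 proliferation marker, was at 279 ± 128 CPM in control and 181 ± 6.49 CPM in LBP (log2 fold change −0.63 ± 0.26, FDR 0.188; −0.18 and 0.0906 without control replicate 1). CCND1 and MYC were not called (log2 fold changes 0.04 and 0.19, FDR 0.863 and 0.698). Without control replicate 1 their log2 fold changes were 0.17 and −0.09, so MYC changed sign, and neither was called (FDR 0.138 and 0.511).

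**Figure D4:**
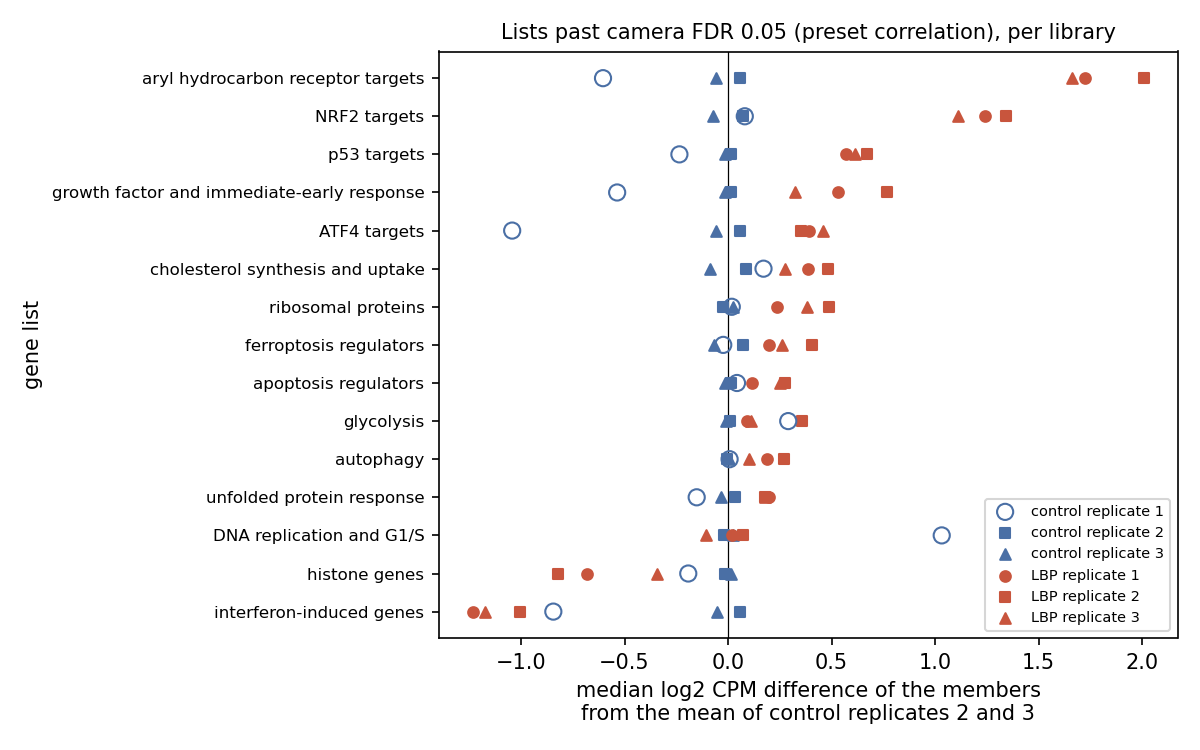
Median log2 CPM difference of each list's members from the mean of control replicates 2 and 3 (horizontal), 1 point per library, for the 15 lists past a camera FDR of 0.05 with the preset correlation. The LBP libraries lie at 1.11 to 1.34 for NRF2 targets, and control replicate 1 lies apart for ATF4 targets (−1.04), interferon-induced genes (−0.84) and DNA replication (1.03).

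Interferon-induced genes were lower in LBP. Of 16 measured members 3 were called lower and none higher (6 lower with the FDR adjusted over the list alone, camera FDR 6.37e-06, adjusted p = 0.262 with an estimated correlation, median −0.91). All 16 had a negative log2 fold change. Besides IFI6, the RNA-sensing synthetase gene OAS3 fell 2.51-fold, from 46.8 ± 5.11 to 18.7 ± 2.74 CPM (FDR 0.00197), and IFI44L fell 4.06-fold (FDR 0.0444). IRF7 had a log2 fold change of −0.72 and was not called (FDR 0.126; 0.00066 without control replicate 1). By fry its adjusted p was 0.0409. Relative to control replicates 2 and 3, the median of this list was −0.84 (log2) in control replicate 1 and −1.23 to −1.01 in the LBP libraries. In this list, control replicate 1 thus lay closer to the LBP libraries than to the other controls. Without control replicate 1, 12 members were called lower, and without LBP replicate 2 only OAS3 was. IFI44L lost its call without each library except control replicate 1 (FDR 0.104 to 0.218).

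Ribosomal protein genes were higher by a small and even amount. Of 32 members 7 rose and none fell, 31 rose with the FDR adjusted over the list alone, and the median log2 fold change was 0.38 (camera FDR 1.59e-12, adjusted p = 0.382 with an estimated correlation). RPS3, RPL5, RPL13 and RPL27 rose 1.41-, 1.37-, 1.35- and 1.36-fold (FDR 0.0337, 0.034, 0.0349 and 0.0413). The adjusted p by fry was 0.0246. Without control replicate 1, 30 members rose, and without each other library none was called (FDR of the 4 genes 0.073 to 0.205). The 86 ribosomal protein genes took 4.83 ± 0.212% of all counts in control and 5.91 ± 0.415% in LBP (SD, n = 3; exact 2-sided permutation p 0.1, the smallest that 3 against 3 libraries can give; adjusted p 0.7 over 7 shares compared). The share of mitochondrially encoded genes was 10.9 ± 0.994% and 10.6 ± 0.242% (exact permutation p 0.6), that of histone genes 0.0474 ± 0.00586% and 0.0518 ± 0.00288% (exact permutation p 0.5), that of the 10 most abundant genes 12 ± 1.39% and 12.5 ± 0.0655% (exact permutation p 1) and that of genes that are not protein-coding 4.28 ± 1.30% and 4.61 ± 0.152% (exact permutation p 0.9). In control replicate 1 the last of these shares was 2.80%, against 4.74% and 5.28% in control replicates 2 and 3, and mitochondrial rRNA took 0.887%, against 1.99% and 2.26%.

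Genes of cholesterol synthesis and uptake were higher, with 7 of 24 measured members rising and none falling (11 higher with the FDR adjusted over the list alone, camera FDR 2.11e-05, adjusted p = 0.356 with an estimated correlation, median 0.35). The low-density lipoprotein receptor gene LDLR rose 1.63-fold (FDR 0.00953), INSIG1 1.90-fold (FDR 0.0118), MSMO1 1.86-fold (FDR 0.0175) and MVD 1.70-fold (FDR 0.0199). The list had an adjusted p of 0.041 by fry. Leaving out control replicate 1, 14 members rose, without control replicates 2 and 3 only 4 and 2, and without LBP replicates 1 and 2 none, where these 4 genes had an FDR of 0.0607 to 0.112. MSMO1 and MVD also lost the call without control replicate 3 (0.0568 and 0.0613), and MVD without control replicate 2 (0.0556). In the glycolysis list 4 of 19 members rose and none fell (5 higher with the FDR adjusted over the list alone, camera FDR 0.0498, adjusted p = 0.694 with an estimated correlation, median 0.03, or −0.04 with total counts only). The aldolase genes ALDOC and ALDOA, both of which share their span with another gene, rose 3.32- and 2.02-fold (FDR 0.00303 and 0.0272), PFKFB3 1.51-fold (FDR 0.0277) and GPI 1.64-fold (FDR 0.0292). Fry gave 0.189, and the list lost its camera call without control replicate 2 (0.171), control replicate 3 (0.18) and LBP replicate 2 (0.111), and with total counts only (0.0554) or the stricter filter (0.0573). Of the 4 genes only ALDOC kept its call with each library left out; the other 3 kept it only without control replicate 1 (FDR 0.0556 to 0.166 otherwise), where 7 members rose and 1 fell.

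Stress-response lists other than NRF2 rested on few called genes. Of 24 ATF4 targets, genes of the integrated stress response, only the stress sensor gene SESN2 was called (2.02-fold higher, FDR 0.00317). With the FDR adjusted over the list alone, 3 were called higher. The log2 fold change was positive for 23 members and negative for 1. The median was 0.64 and the camera FDR 3.47e-07 (adjusted p = 0.485 with an estimated correlation). DDIT3, CEBPB and ATF3 had log2 fold changes of 0.99, 0.70 and 1.58 (FDR 0.0537, 0.0654 and 0.106) and were called without control replicate 1 (0.00181, 0.000153 and 0.000251), DDIT3 also without control replicate 2 (0.0399). Fry gave the ATF4 list 0.159. Control replicate 1 lay 1.04 (log2) below the other controls in its median, and without it the median was 0.40 and 17 members rose; without control replicate 2, 2 rose. Of 18 genes of the unfolded protein response only HSPA5, the endoplasmic reticulum chaperone BiP, was called (1.69-fold higher, FDR 0.00996, and 0.0696 without LBP replicate 2). The same held with the FDR adjusted over the list alone (camera FDR 0.0116, adjusted p = 0.485 with an estimated correlation, median 0.25). HYOU1, MANF and ERN1 had log2 fold changes of 0.37, 0.36 and 0.61 (FDR 0.0902, 0.0993 and 0.113), and the fry value was 0.0745. Of this list 6 members rose without control replicate 1, among them HYOU1, MANF and ERN1 (FDR 0.00967, 0.0244 and 0.00398), at log2 fold changes of 0.30, 0.31 and 0.38. In the autophagy list 4 of 22 rose and none fell (6 higher with the FDR adjusted over the list alone, camera FDR 0.00104, adjusted p = 0.262 with an estimated correlation, median 0.14): the autophagy receptor gene SQSTM1 2.07-fold (FDR 0.00384), MAP1LC3B 1.56-fold (FDR 0.028), GABARAPL1 2.44-fold (FDR 0.0439) and ATG9A 1.34-fold (FDR 0.0496). By fry the autophagy list had 0.0246. With control replicate 1 left out, 7 members rose, and without each other library only SQSTM1 did (FDR of the other 3 genes 0.0626 to 0.225).

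The growth factor and immediate-early list was called higher (camera FDR 2.66e-07, adjusted p = 0.262 with an estimated correlation, median 0.67), with 3 of 20 members rising and none falling, and 13 rising with the FDR adjusted over the list alone. SPRY4, an inhibitor of receptor tyrosine kinase signalling, and the transcription factor genes ETV5 and ETV4 rose 7.34-, 6.60- and 5.91-fold (FDR 0.0124, 0.0143 and 0.034) from low levels of 0.205 ± 0.041, 0.245 ± 0.0579 and 0.538 ± 0.412 CPM. The log2 fold change of ETV4 was 2.56, and 3.37 without control replicate 3. JUN had a log2 fold change of 0.91 (FDR 0.0652; 0.0288 without control replicate 1). Fry gave the list 0.0246. Without control replicate 1, 13 members rose, without control replicate 2 only 1, and without LBP replicates 1, 2 and 3 none. SPRY4, ETV5 and ETV4 lost their calls without control replicate 2 or any LBP replicate (FDR 0.0507 to 0.198). Control replicate 1 lay 0.54 below the other controls in the median of this list. Of 12 histone genes HIST1H2AC and HIST1H2BD fell 1.62- and 1.51-fold (FDR 0.0325 and 0.0333), none rose, and 1 was higher and 4 lower with the FDR adjusted over the list alone (camera FDR 0.0284, adjusted p = 0.382 with an estimated correlation, median −0.65). HIST1H2BG and H1F0 had log2 fold changes of −0.73 and 0.55 (FDR 0.0568 and 0.0649; 0.000659 and 0.00099 without control replicate 1). By fry the histone list had 0.0509, and the camera call was lost without control replicates 2 and 3 (0.0841 and 0.0605), without LBP replicates 1 and 2 (0.0807 and 0.0551) and with total counts only (0.0516). Histone genes share sequence, and both calls were held only without control replicate 1 (FDR 0.0579 to 0.192 otherwise), where 1 member rose and 6 fell.

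Oestrogen receptor alpha, ESR1, fell 1.96-fold, from 172 ± 54.6 to 87.7 ± 8.10 CPM (FDR 0.0288), and lost the call without each LBP replicate (FDR 0.0984 to 0.192). Its log2 fold change was −0.97, and a smaller −0.67 without control replicate 1 (edgeR FDR 8.7e-06). The oestrogen-induced genes were not called as a list (camera FDR 0.65, median −0.08), although they were called lower without control replicate 1 (camera FDR 0.0434, adjusted p = 0.734 with an estimated correlation, 9 members lower and 2 higher), which lay 0.88 (log2) below the other controls in their median. Of 25 members only ELOVL2, a fatty acid elongase gene, was called (3.02-fold lower, FDR 0.0358). This call was held only without control replicate 1 (FDR 0.0931 to 0.183 otherwise). With the FDR adjusted over the list alone 2 were called lower. SGK3 had a log2 fold change of −1.16 (FDR 0.0506; 0.000136 without control replicate 1), and the classical targets TFF1 and PGR of −0.46 and −1.67 (FDR 0.421 and 0.167; 0.0071 and 0.00307 without control replicate 1, at −0.78 and −2.07). Of 19 luminal epithelial genes 1 rose and 2 fell (4 higher and 3 lower with the FDR adjusted over the list alone, camera FDR 0.679, median −0.02; 5 higher and 3 lower without control replicate 1): the tight junction gene CLDN4 rose 1.91-fold (FDR 0.0064; 0.0548 without LBP replicate 2), and ESR1 and the mucin gene MUC1 fell, MUC1 by 0.65 on the log2 scale (FDR 0.025; 0.0658 without control replicate 3, and 0.0769 to 0.166 without each LBP replicate). Of 12 mesenchymal and wound genes TGFBI rose 5.6-fold (FDR 0.0194) and S100A4 fell 2.00-fold (FDR 0.0215), as with the FDR adjusted over the list alone (camera FDR 0.679, median 0.05, or −0.03 with total counts only), and 1 rose and 2 fell without control replicate 1. S100A4 kept its call only without control replicate 1 (FDR 0.0569 to 0.116 otherwise), and TGFBI lost it without control replicate 2 and LBP replicates 1 and 2 (0.0618, 0.0515 and 0.0929). The log2 fold change of TGFBI was 2.49, and 1.87 without LBP replicate 2.

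Of the basal and myoepithelial list 6 of 13 genes were measured and none was called, over all genes or over the list alone (camera FDR 0.719, median −0.11); ITGA6 and LAMB3 had log2 fold changes of 0.91 and −0.58 (FDR 0.0952 and 0.251; 0.025 and 0.0382 without control replicate 1, where 2 members were higher and 1 lower). Only 2 fibroblast, 1 leukocyte and 4 endothelial markers were measured, too few for a list test. COL1A1 and COL6A3 (FDR 0.909 and 0.987; COL1A1 called lower without control replicate 1, 0.0448, at a log2 fold change of −0.33 against −0.06) and CD19 (FDR 0.455) were not called, nor was ESAM (FDR 0.372). The endothelial cadherin gene CDH5 had no count in the 3 control libraries and 37, 32 and 18 counts in LBP replicates 1, 2 and 3, at least 29.4-fold higher against a floor of 3 counts over the control group (FDR 0.00743; 0.0663 without LBP replicate 2).

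Of the remaining lists none was called by camera, and in 6 of them, the heat shock list below among them, no member passed over all genes or over the list alone: hypoxia-induced genes (FDR 0.234; PDK1 and LOX, log2 fold changes 0.50 and −0.91), the nuclear-encoded respiratory chain (0.679; COX5A and UQCRC1, 0.30 and 0.22), mitochondrially encoded mRNAs (0.749; MT-CYB and MT-ATP8, −0.18 and 0.22), metallothioneins (0.749; MT1X and SLC39A10, 0.92 and −0.45) and nucleotide synthesis (0.679; PRPS1 and TYMS, 0.72 and −0.57). With control replicate 1 left out, LOX (FDR 0.0256) and SLC39A10 (0.00052, at a log2 fold change of −0.70) were called lower and COX5A (0.00809), UQCRC1 (0.0354), MT1X (0.0459) and PRPS1 (3.75e-05) higher, while TYMS was at −0.32 and not called (0.0879). In that comparison 3 hypoxia-induced genes were lower, 2 respiratory chain genes higher and 1 lower, 1 gene of the metallothionein list higher and 1 lower, 3 nucleotide synthesis genes higher and 1 lower, and no mitochondrially encoded mRNA was called. The heat shock list was not called (FDR 0.712; DNAJB1 and HSPA4L, 0.77 and 0.33), but it was called higher without control replicate 1 (0.00242, adjusted p = 0.663 with an estimated correlation), where 6 members rose, HSPA4L among them (FDR 0.00941). Control replicate 1 lay 0.83 (log2) above the other controls in the median of this list. Ribosome biogenesis genes (FDR 0.176; RRP12 and GNL3, 0.40 and 0.38; 0 members called over all genes and 2 higher over the list alone) were likewise called without it (0.0253, adjusted p = 0.674 with an estimated correlation; RRP12 and GNL3, FDR 0.00148 and 0.00132), with 5 members higher and 1 lower. In the fatty acid synthesis list 2 of 16 rose, also over the list alone (camera FDR 0.166; 4 higher and 3 lower without control replicate 1), the malic enzyme gene ME1 2.06-fold (FDR 0.00213) and ACSS2 1.86-fold (FDR 0.0482; 0.0551 to 0.218 with any library left out). In the lysosome list 2 of 22 rose, or 3 over the list alone (camera FDR 0.251; 3 higher and 3 lower without control replicate 1), the cholesterol transporter gene NPC1 1.60-fold (FDR 0.0278) and NEU1 1.34-fold (FDR 0.0439). NFKB2 rose 1.5-fold (FDR 0.0337) among 11 NF-kB targets (camera FDR 0.195; 2 higher and 1 lower over the list alone, 2 and 2 without control replicate 1), of which ICAM1 had a log2 fold change of 0.92 (FDR 0.0608; 0.00222 and 0.0461 without control replicates 1 and 3). The insulin receptor gene INSR rose 1.61-fold (FDR 0.0189) among 21 genes of IGF, PI3K and mTOR signalling (camera FDR 0.65; 1 higher over the list alone, 6 higher and 2 lower without control replicate 1), of which FOXO1 had a log2 fold change of 0.74 (FDR 0.115; 0.0285 without control replicate 1). Among 7 osmotic stress targets (camera FDR 0.679; 1 higher and 2 lower over the list alone and without control replicate 1) the taurine transporter gene SLC6A6 rose 1.81-fold (FDR 0.0109) and SLC6A12 fell. Of these called genes only ME1, which also belongs to the NRF2 list, kept its call with each library left out. Without LBP replicate 2 the others had an FDR of 0.0816 to 0.218. NEU1 and NFKB2 kept the call only without control replicate 1 (0.0534 to 0.188 otherwise), NPC1 and INSR lost it also without LBP replicates 1 and 3 and control replicate 3 (0.0579 to 0.115), and SLC6A6 without LBP replicate 1 (0.0634).

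Over the 32 tested lists 15 were called by camera with the preset correlation, 12 higher and 3 lower. None was called with an estimated correlation, where the smallest adjusted p was 0.134, and fry called 10. Camera with the preset correlation also called 5 to 13 lists in each of the 9 other ways to split the 6 libraries into 3 and 3. Of the 15 lists only 9 had their smallest p in the real split. The lists of DNA replication, ATF4 targets, interferon-induced genes, glycolysis, the unfolded protein response and histone genes had a smaller p in at least 1 other split. The direction of camera, which compares a list with all other genes, differed from the sign of the median in the basal, luminal, heat shock and respiratory chain lists, none of them called.

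The authors' deposited table gave 1318 genes with an adjusted p below 0.05, 686 higher and 632 lower. Of the 755 genes called here, 743 were among them, all in the same direction, and 12 were not. At least 2-fold changes numbered 411 in the authors' deposited table and 304 here, with 287 shared.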

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

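No alternative was chosen after the data were seen. Directions held for all 743 genes shared with the authors' deposited table and for the 71 called genes of the naming rule under each setting in which they were tested. The 755 changed genes became 1687 with no filter on low counts, 1320 with DESeq2 and 149 at an FDR below 0.01, and ran between 648 and 868 under the other scalings, the stricter filter and limma-voom. The 304 genes changed at least 2-fold became 526 with no filter and 104 when tested against a 1.5-fold change. Leaving out each library in turn gave 104 to 4118 changed genes, 84 to 804 genes changed at least 2-fold and 12 to 17 called lists. With an estimated correlation 0 lists were called. The DNA replication and G1/S list lost its call without control replicate 1 (camera FDR 0.813, against 0.000185 without control replicate 2 and 0.075 without LBP replicate 3). The direction of camera turned there, while the median of the list was −0.01. The share of the 10 most abundant genes differed by 0.482 percentage points, or 1.52 with mitochondrially encoded genes left out. The genes shared with the authors' deposited table numbered 743, or 287 with a change of at least 2-fold. A stricter threshold gives fewer calls by its construction; for the other moves the cause was not tested. Of the 71 called genes named, 27 kept their call with every library left out; 65 kept it with total counts only and 64 with limma-voom. At this depth 70% of simulated 2-fold changes were recovered, so missed calls do not show that genes were unchanged.

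With the replicate number as a block, 685 genes were called, 577 of them among the 755, with 318 changed at least 2-fold and 14 lists called. Deviations of same-numbered libraries were correlated at −0.02, −0.09 and 0.05, against −0.05 to 0.07 for other pairs. Not every library correlated best with its own number. The deviations were taken from group means, and control replicate 1, which stood apart, pulls the mean of the controls. These values therefore cannot exclude a pairing. The labels state none, and none was used in the main test. Of the named genes, 9 were called without the block and not with it, and 8 the other way round. The glycolysis list was not called with the block (camera FDR 0.0728).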

Other observations

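The genes in this and the next paragraph, apart from ID1, were chosen after their values were seen, also those that belong to the NRF2 list (TXNRD1, OSGIN1, AKR1C1 and AKR1C2) or the aryl hydrocarbon receptor list (CYP1A2 and UGT1A6), as were MEG9, FTLP12 and FTLP14 below. The 3 tested members of the ID family, inhibitors of basic helix-loop-helix transcription factors, were all lower in LBP. ID1 fell 6.78-fold, ID2 3.43-fold, from 41 ± 1.68 to 12 ± 0.852 CPM (SD, n = 3; edgeR FDR 0.000236), and ID3 4.28-fold, from 55 ± 11 to 12.9 ± 5.69 CPM (FDR 0.00529). All 3 kept their calls with each library left out. The pregnancy-specific glycoprotein genes PSG9 and PSG4 on chromosome 19 were higher, and their family was not tested as a whole. PSG9 rose from 0.408 ± 0.336 to 9.51 ± 4.97 CPM (FDR 0.00324). Its log2 fold change was 4.51, and 5.42 without control replicate 2. PSG4 had 3 counts over the control group, below the floor of detection in each library, and 102 over the LBP group (FDR 0.0112). The ratio relative to total counts was 34.5 (exact 95% interval 11.5 to 170), or 69.2 (12.2 to 2760) without control replicate 2. These intervals were computed on counts summed over each group and cover counting error only. They leave out the spread between libraries, with a level of 2.24 ± 1.30 CPM in LBP (SD, n = 3). PSG4 lost its call without LBP replicates 1 and 2 (FDR 0.0509 and 0.0795), and the genes of this family are similar in sequence.

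UDP-glucose dehydrogenase, UGDH, rose 3.49-fold (FDR 0.000913), the efflux transporter gene ABCG2 2.21-fold (FDR 0.00211), CYP1A2 11.2-fold (FDR 0.00181) and UGT1A6, which shares exons with other UGT1A genes, 6.06-fold (FDR 0.00472), while the glucuronosyltransferase gene UGT2B15 fell 5.65-fold (FDR 0.0055) and the sulfate transporter gene SLC26A2 fell 4.61-fold, from 192 ± 20.6 to 41.7 ± 13.4 CPM (FDR 0.00104). All of these, with TXNRD1 (3.39-fold higher; FDR 0.000524) and OSGIN1 (4.56-fold higher; FDR 0.000524), kept their calls with each library left out. The aldo-keto reductase genes AKR1C1, AKR1C2 and AKR1C3 rose 4.64-, 4.93- and 3.83-fold (FDR 0.016, 0.018 and 0.0338). All 3 lost the call without control replicate 3 and LBP replicates 1 and 2, and AKR1C1 and AKR1C3 without LBP replicate 3 as well (FDR 0.0579 to 0.192). Without control replicate 2 the log2 fold changes of AKR1C1 and AKR1C3 were 2.93 and 2.65, against 2.21 and 1.94. CBR3 rose 2.47-fold (FDR 0.0176) and kept its call only without control replicate 1 (0.0511 to 0.0976 otherwise). A search over 419 families of genes that share a symbol stem, also chosen after the data were seen, gave 10 called families by camera with the preset correlation and 0 with an estimated correlation (smallest adjusted p 0.994).

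Of the tests below, those of the count of changed genes over splits, of a wrong label and of other cell types were chosen only after the result was seen. The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. Each split other than the real one also mixes control and LBP libraries in both groups. A difference between LBP and control then widens the spread within groups and lowers the count of changed genes. The gene counts of these splits therefore do not show what chance gives. The real split gave 755 changed genes and the highest other 0, 304 and 0 genes changed at least 2-fold, and 15 and 13 called lists, so that 1 split of 10 was as high as the real one in each case.

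Control replicate 1 stood apart from the other controls, the labels give no treatment, time or other group that sets it apart from them, and no biological explanation was tested. A wrong label would place NRF2 and aryl hydrocarbon receptor targets at the level of LBP. However, their median difference from control replicates 2 and 3 was −0.012 in control replicate 1, against 1.19 to 1.47 in the LBP libraries. In control replicate 1, 26 of 28 members lay below every LBP library. These lists had the largest median fold changes with control replicate 1 counted as a control, which favours a control-like value in it. Other cells would have to make up at least 8.56% (12.4% and 12.9% of counts were placed differently from the other controls, less 3.81% between these), at which 11 of 12 fibroblast markers (all but COL1A1) and 19 of 22 leukocyte and endothelial markers could reach at most a level below the median tested gene, 18.1 CPM, in those cells, which argues against fibroblasts, leukocytes and endothelial cells. This bound replaced marker sums after their values were seen: 1 sum that held basal markers (alone at 104.64 against 89.82 and 90.1 CPM), then fibroblast markers (25.9 against 52 and 53.6, or 1.49 against 2.08 and 2.71 without COL1A1, which alone does not decide) and leukocyte and endothelial markers (10.4 against 11.2 and 9.77, which could not tell). A smooth trend in GC content and gene length took up 3.73% of the variance and left the root mean square difference at 0.68 (0.693 before; 0.375 between control replicates 2 and 3), which argues against this bias, while a difference in culture state or handling, not tested, stays open.

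FTH1 rose 4.10-fold and 5 of 6 tested FTH1 pseudogenes were called higher, with a median log2 fold change of 2.63 over the 6 against 2.04 for FTH1. Over 339 other processed pseudogenes, the fold change followed that of the parent gene (Spearman rho 0.338; 95th percentile of 10000 random pairings 0.0907; permutation p 1e-04, the smallest possible). Many of these pairs belong to ribosomal protein genes, which were higher together, and several copies share a parent. The random pairings broke up these groups, so the permutation p does not tell copies following their parents from a family that moved together. Reads of the parent counted on its copies would give such a correlation. The 5 called copies rose by 2.54 to 3.00 (log2, SE 0.33 to 0.57), against 2.04 ± 0.12 for FTH1. Beside these errors the difference is too small to show that the copies rose more than FTH1. FTLP12 and FTLP14, copies of FTL, had −0.08 and 0.24 against 1.22 for FTL and were not called (FDR 0.946 and 0.634). FTH1P3, with a log2 fold change of −0.06 (FDR 0.96), lies within PPM1G and was not called. Transcription of the pseudogenes themselves was not tested and stays open.

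DLK1 (chromosome 14, 100725705 to 100738224), MEG3 and MEG9 (101064151 to 101072937) lie in an imprinted region, and all 3 fell. They are the only tested genes from the start of DLK1 to the end of MEG9. Both ends of that span were set by genes that fell, and genes beyond it were not examined. The values therefore do not show that the whole region fell. DLK1 fell 7.07-fold and MEG3 8.97-fold, and MEG9 had 42 counts in control and 0 in LBP, at least 13.8-fold lower against a floor of 3 counts over the LBP group (FDR 0.0167), though it kept its call in only 2 of the 6 cases with a library left out. Over the genome, 45 of 12415 pairs of neighbouring genes that do not overlap were called in the same direction, against a mean of 13.8 (7 to 21 in 95%) in 10000 random placements (1-sided permutation p 1e-04, the smallest possible), while 9 pairs were called in opposite directions (mean 13.9). Only 6 of the 45 pairs share a symbol stem. The hypothesis that neighbouring genes changed together more often than random placement gives fits these values, which do not tell shared regulation from reads that run past the end of a gene.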
